A study of Arabidopsis thaliana with 6 samples.

How the data were processed

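Gene expression was compared between 5-day-old whole Arabidopsis thaliana seedlings of 3 overexpression lines and wild type Col-0 on 6 two-colour oligonucleotide arrays, 2 per line. Each array held a transgenic line in one dye and wild type in the other. Replicate 1 of each line had the line in Cy5 and replicate 2 had it in Cy3, per the labels. Seedlings were grown in hydroponic medium at 25 °C with 12 h light and 12 h dark, and 200 ng of total RNA was amplified and labelled, per the labels' protocols. No salt or drought treatment is named in the labels.

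The arrays were of Agilent design 021169 and were quantified with Feature Extraction 10.7.3.1, per the file headers. The deposited scanner files give for each spot the median intensity of the spot and of its local background in both channels, in scanner units with no further treatment, per the file headers. They also give processed intensity values, background-subtracted and dye-normalised by the scanner software, and the log10 ratio of Cy5 over Cy3 computed from these, per the file headers. The deposited value table was set against each array's scanner log10 ratio. On 100% of spots of each array the values lay within 0.006 of it after the sign was turned on replicate 2, so the table holds log10 of line over wild type, rounded. Its median was 0 on each of the 6 arrays, with no further centring.

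The median intensities of 43803 spots were background-corrected with normexp (offset 50) and normalised within each array by loess in limma 3.58.1 under R 4.3.3. The plan had named mean foreground signals; the scanner files hold median signals, which were used in their place. Control spots and spots with an outlier mark (77 spots on any array) had a weight of 0 in the loess and were then left out. Each ratio was expressed as line over wild type, and spots of a probe were averaged. A probe was kept when it was well above background in 1 genotype on both arrays of at least 1 line, which left 28327 of 43603 probes. The probe brightest on average stood for its gene, which gave 21320 genes, of which 5416 had several probes. Of the genes, 19602 had a locus identifier and 1718 were other transcript identifiers of the array design. Symbols came from the reference table of assembly TAIR10.1, in which 19423 of the loci were found. That table was used for names and neighbours only and no coordinates are given.

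Median spot intensity was 68.5 to 98 in red and 82 to 114 in green, against median local backgrounds of 54 to 55 and 25 to 33. Between 49.7% and 63.0% of spots were well above background in red and between 67.4% and 71.8% in green. No spot was saturated (0 on each array), and the slope of observed on expected spike-in log ratios was 0.802 to 0.851. The number of arrays limits the precision.

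Each line was tested against wild type with limma's moderated test on log2 ratios, with 1 coefficient per line and all 6 arrays in 1 fit (3 residual and 4.03 prior degrees of freedom). Benjamini-Hochberg adjustment was made over genes within a comparison, and a gene was called at an adjusted p under 0.05. Differences between lines were tested as contrasts in the same fit. All p-values are two-sided and measure the spread between these samples only. Errors are standard errors of the fit. Of the called genes with several probes, all probes had the direction of the brightest for 70 of 71 in 35S:ERF019, 108 of 111 in 35S:BBX29 and 391 of 399 in 35S:CCA1.

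Replicate number and dye orientation are the same factor here. Deviations of same-numbered arrays from their line's mean correlated across genes at r = 0.427 (35S:ERF019 with 35S:BBX29), 0.836 (35S:ERF019 with 35S:CCA1) and 0.449 (35S:BBX29 with 35S:CCA1). The log2 ratios of a line's 2 arrays correlated across genes, which are not independent replicates, at r = 0.163 for 35S:ERF019, 0.611 for 35S:BBX29 and 0.469 for 35S:CCA1, and those of same-numbered arrays of different lines at 0.485 to 0.623. The fit with the replicate number as a block, called the block below, had 2 residual and 9.81 prior degrees of freedom, and its values stand beside a result where they change the call or move a count by over 1.5 times. The arrays lay on 2 slides, 35S:ERF019 and 35S:CCA1 on slide 1 and 35S:BBX29 on slide 2, and each slide was scanned as 1 batch. The design text names 2 wild type replicates, and whether the lines shared wild type RNA is not stated.

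Before the data were examined, 26 gene lists were fixed, holding 365 entries of which 328 were tested. They covered the clock (morning-phased and evening-phased), photoperiodic flowering, PIF targets and growth, abscisic acid (ABA) and dehydration effector genes, ABA signalling and stress transcription factors, the cold and CBF regulon, sodium and potassium transport, ethylene, jasmonate, salicylic acid and pathogen defence, flavonoids, the B-box family, light-harvesting antenna, chlorophyll synthesis, starch turnover, dark and sugar starvation, antioxidant enzymes and glutathione transferases, wax and suberin, iron, phosphate starvation, heat shock and glucosinolates. Tissue markers for root hairs, seed storage and oil bodies, and seed reserve mobilisation were added to these. The seed storage list had 1 of 10 members measured and was not tested. Lists were tested with camera at a preset correlation of 0.01, and again with a correlation estimated within each list, adjusted over 25 lists and 3 lines. None of the list calls (0 in each line) held with the estimated correlation. The estimate lay below the preset value for root hairs (-0.088), jasmonate (-0.044) and salicylic acid and pathogen defence (-0.023). It lay above the preset value for others, such as glucosinolates (0.033). Where it lay below, a higher correlation within the list did not cause the loss. For root hairs in 35S:CCA1 the unadjusted camera p was 4.92e-12 at the preset value and 0.00563 with the estimate. Adjusted over the 75 list results, the latter became 0.211. A call lost in this way does not show that the list's members were correlated. Median, mean and test differed in sign in 6 of 75 list results, of which 0 were called. A further 6 lists were written after the changed genes had been seen and were adjusted apart, over those 6 lists and 3 lines.

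Named genes are the targeted gene, the 10 largest called rises and 10 largest called falls with a locus identifier and the same direction on both arrays, up to 4 called members of each list, and for called lists the 2 largest members not called. SOS1, HKT1, NHX1, RD29A, RD29B and RAB18 were named for every line and 8 core clock genes for 35S:CCA1. HKT1, RD29B and PRR9 were not well above background on enough arrays to be kept. A gene that the rule names is not reported here. Where a probe was not well above background in 1 genotype on both arrays, the fold is a lower bound, the bright genotype's mean over the higher of the array's detection floor and the probe's own signal.

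The fit was tested on 20 simulated data sets with the real dye effects, each with 21320 genes of which 200 were changed per comparison. It recovered 25.3% of log2 changes of 1 for 35S:ERF019, 29.9% for 35S:BBX29 and 29.3% for 35S:CCA1, and 96.3%, 97.2% and 97.2% of changes of 2. False calls made up 0%, 0.0791% and 0% of its calls. With the block, 98.5%, 98.6% and 98.6% of changes of 1 were recovered, with 4.61%, 4.73% and 4.84% false calls. The simulated noise was independent between arrays, with no wild type RNA shared between lines. If the lines shared wild type RNA, the block would take its spread out of the residual. The false call rate with the block may then not hold for these data. A list of 20 genes shifted by 1 was found in each comparison, and 1, 2 and 3 of 100 unchanged lists had an unadjusted p under 0.05.

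Alternatives were the block, a block within slide, only the arrays of a line's slide, only the line's 2 arrays, no background subtraction, the scanner's processed signals, median centring in place of loess, the deposited value table, no filter or a stricter one on dim probes, the mean of a gene's probes, other thresholds, an estimated correlation, and leaving out each array. For the overlap of lines, 100 sets of unchanged lines sharing wild type RNA were simulated. Promoter motifs were planned but not analysed here.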

Results

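The data set held 6 arrays of RNA from whole seedlings, 2 for each of 3 lines that express a transcription factor from the strong 35S promoter of cauliflower mosaic virus. 35S:ERF019 overexpresses ERF019 (AT1G22810), a factor of the ethylene response factor family. 35S:BBX29 overexpresses BBX29 (AT5G54470), a B-box zinc finger protein, and 35S:CCA1 overexpresses CCA1 (AT2G46830), a MYB-related factor of the circadian clock. Every array set 1 line against wild type, so each line has 2 ratios, 1 in each dye orientation. The stated aim was to learn how these factors, chosen for their induction by salt, alter expression across the genome, in relation to salt and drought tolerance. Values below are log2 ratios of line over wild type from 2 arrays each, with the standard error where given, and adjusted p-values are from limma.

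Each transgene's transcript was raised in its own line on both arrays. ERF019 was 26.6-fold higher in 35S:ERF019 (4.73 ± 0.23, adjusted p = 0.00146), with 4.31 and 5.16 on its arrays. BBX29 was 78.0-fold higher in 35S:BBX29 (6.29 ± 0.22, adjusted p = 0.000363), with 6.76 and 5.81. CCA1 was 53.0-fold higher in 35S:CCA1 (5.73 ± 0.15, adjusted p = 4.01e-05), with 5.56 and 5.89. Another CCA1 probe gave 3.71, and a further one, not well above background in wild type on either array, read 2.14, a value limited by background. The mean of its probes was 3.86. In the other lines the ERF019 transcript stood at -1.02 and -0.97 on the 35S:BBX29 arrays (adjusted p = 0.106, 0.000818 with the block) and fell by 1.58 in 35S:CCA1 (adjusted p = 0.0109). The BBX29 and CCA1 transcripts were not called in the lines that overexpress another factor. After median centring in place of loess these calls were lost, with log2 ratios of 4.83, 6.15 and 5.57.

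**Figure D1:**
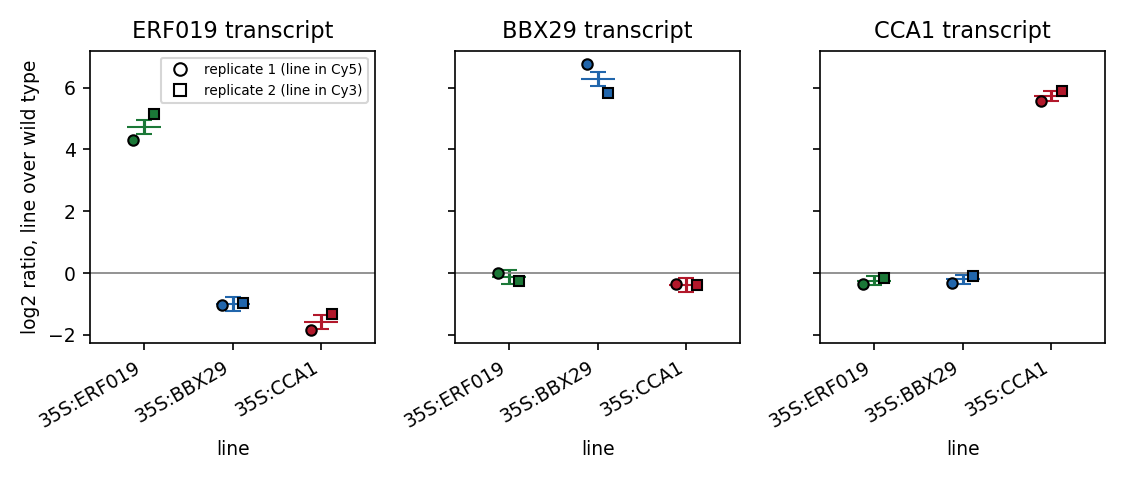
Log2 ratio of line over wild type (vertical axis) for the ERF019, BBX29 and CCA1 transcripts in the 3 lines (horizontal axis), with a circle for replicate 1, a square for replicate 2, and a bar for the mean with its standard error. Each transcript lies far above 0 in its own line alone, at 4.73, 6.29 and 5.73.

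The comparison of 35S:ERF019 with wild type asked which genes follow raised ERF019. VSP1 and VSP2, vegetative storage proteins, rose 4.26-fold (2.09 ± 0.16) and 4.23-fold (2.08 ± 0.34). CORI3, a lyase induced by the jasmonate mimic coronatine, rose by 1.96, NATA1, which acetylates ornithine, by 1.89, and TGG2, a myrosinase that cleaves glucosinolates, by 1.83. PCC1, a small protein under clock and pathogen control, was 23.3-fold lower (-4.54 ± 0.23, adjusted p = 0.00146), and WRKY70, a regulator between salicylic acid and jasmonate responses, fell to -2.11 ± 0.30 (adjusted p = 0.0338).

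Among the other largest rises in 35S:ERF019 were AT5G61620 (2.43, well above background on 1 of 2 wild type channels), AT3G28220 (2.17), AT3G43270 (1.97) and AT3G59710 (1.86). The other largest falls were AT3G22235 (-3.03), which lies near PCC1, AT5G42530 (-2.72), AT2G25510 (-2.33), AT5G38910 (-2.02, well above background on 1 of 2 line channels) and AT2G43140 (-1.89). OSM34, an osmotin-like protein, DR4, a drought-repressed protease inhibitor, and MSRB8, a methionine sulphoxide reductase, fell to -1.95, -1.81 and -1.79.

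The salicylic acid and pathogen defence list showed 4 lower of 17 members (8 lower adjusted over the list alone, 9 lower with the block). The set fell (median -0.62, camera adjusted p = 1.84e-10, adjusted p = 0.211 with an estimated correlation). Its members included the transcription factors WRKY70 and WRKY40 (-1.27) and the pathogenesis-related proteins PR5 (-1.01) and PR2. PR2 was well above background on neither line channel and was at least 2.00-fold lower. The regulator CBP60G stood at -0.96 (adjusted p = 0.0810, 0.000577 with the block) and the monooxygenase FMO1 at -0.93 (adjusted p = 0.0530, 0.000407 with the block). The jasmonate list showed 2 higher of 18 members (6 higher and 1 lower adjusted over the list alone, 6 higher and 1 lower with the block). The set rose (median 0.17, camera adjusted p = 0.00163, adjusted p = 0.223 with an estimated correlation). Besides VSP1 and VSP2, the lipoxygenase LOX2 stood at 1.15 (adjusted p = 0.133, 0.000383 with the block) and the repressor JAZ9 at 0.73 (adjusted p = 0.123, 0.00774 with the block).

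Flavonoid and anthocyanin genes showed 0 higher and 0 lower of 20 members (1 higher adjusted over the list alone, 8 higher with the block). The list was higher (median 0.41, camera adjusted p = 0.000128, adjusted p = 0.271 with an estimated correlation). The glycosyltransferase UGT78D2 stood at 0.75 (adjusted p = 0.0530, 0.00189 with the block) and the flavonol synthase FLS1 at 0.66 (adjusted p = 0.293, 0.00925 with the block). Glucosinolate genes showed 0 higher and 0 lower of 18 members (1 higher adjusted over the list alone, 4 higher with the block). They too were higher (median 0.17, camera adjusted p = 0.0108, adjusted p = 0.271 with an estimated correlation), with the cytochrome CYP79F1 at 1.07 (adjusted p = 0.190, 0.000889 with the block) and the regulator MYB29 at 0.84 (adjusted p = 0.105, 0.00260 with the block). Seed reserve mobilisation genes showed 1 higher of 3 members (2 higher adjusted over the list alone). Together they were higher (median 0.38, camera adjusted p = 0.000453, adjusted p = 0.271 with an estimated correlation). ICL, the isocitrate lyase of the glyoxylate cycle, rose by 1.72, PCK1 stood at 0.38 (adjusted p = 0.309) and MLS at 0.27 (adjusted p = 0.903).

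Dark and sugar starvation genes showed 2 higher of 4 members (2 higher and 1 lower adjusted over the list alone, 2 higher and 1 lower with the block). These genes were as a group higher (median 0.67, camera adjusted p = 0.0215, adjusted p = 0.271 with an estimated correlation). This list was not called with the block (adjusted p = 0.0534). Its dark-inducible DIN1 rose by 1.22 and the asparagine synthetase ASN1 by 1.12, while DIN10 stood at -0.74 (adjusted p = 0.379, 0.00479 with the block) and DIN11 at 0.22 (adjusted p = 0.938). ABA signalling and stress transcription factors showed 0 higher and 0 lower of 16 members (1 higher and 1 lower adjusted over the list alone, 3 higher and 1 lower with the block). The list was higher (median 0.27, camera adjusted p = 0.0124, adjusted p = 0.249 with an estimated correlation). Within it ATHB7 stood at 0.83 (adjusted p = 0.0555, 0.00111 with the block) and DREB2A at -0.96 (adjusted p = 0.116, 0.00258 with the block).

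Heat shock genes showed 0 higher and 0 lower of 9 members (3 lower adjusted over the list alone, 5 lower with the block). The set was lower (median -0.55, camera adjusted p = 0.000516, adjusted p = 0.223 with an estimated correlation). The chaperones HSP101 and HSP17.6C stood at -0.81 (adjusted p = 0.264, 0.00301 with the block) and -0.77 (adjusted p = 0.148, 0.00195 with the block). Phosphate starvation genes showed 1 lower of 6 members (3 lower adjusted over the list alone, 3 lower with the block). Together they were lower (median -0.46, camera adjusted p = 0.000374, adjusted p = 0.223 with an estimated correlation). The non-coding RNA IPS1 fell to -1.15, the transporter PHT1;1 stood at -1.01 (adjusted p = 0.308, 0.000348 with the block) and the non-coding RNA AT4 at -0.68 (adjusted p = 0.249, 0.0160 with the block). The cold and CBF regulon showed 1 higher of 12 members (1 higher and 3 lower adjusted over the list alone, 1 higher and 4 lower with the block). As a set they were nonetheless lower (median -0.19, camera adjusted p = 0.0277, adjusted p = 0.384 with an estimated correlation). Its called member COR15A, a chloroplast cold-regulated protein, rose by 0.92, whereas GOLS3 stood at -1.13 (adjusted p = 0.124, 0.000107 with the block) and ZAT12 at -0.98 (adjusted p = 0.113, 0.000655 with the block).

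The other 15 lists were not called in 35S:ERF019 (camera adjusted p from 0.113 to 0.868), root hair markers among them (median -0.17). Called members of these lists were HFR1 (0.87), the antenna protein LHCB4.3 (-0.96), the glutathione transferase GSTF2 (-0.94), the suberin enzymes CYP86A1 (-1.29) and GPAT5 (-0.93), and the nicotianamine synthase NAS4 (-0.92). Of the salt and ABA genes, the sodium exporter SOS1 stood at 0.07 (adjusted p = 1.00), the vacuolar exchanger NHX1 at 0.33 (adjusted p = 0.419), RD29A at -1.03 (adjusted p = 0.0707, 0.000296 with the block) and the dehydrin RAB18 at 0.40 (adjusted p = 0.557). Across all genes, 242 of 21320 were called in 35S:ERF019, 100 higher and 142 lower, and 1762 with the block, 721 higher and 1041 lower. Across genes, the log2 ratios of its 2 arrays correlated at r = 0.163, and those of same-numbered arrays of 35S:ERF019 and another line at 0.485 to 0.612. On the arrays of its own slide alone 5 were called, without replicate 1 or 2 of the line 9 and 14, and after median centring in place of loess limma called 0, with 137 at an unadjusted p under 0.05.

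The comparison of 35S:BBX29 with wild type asked which genes follow raised BBX29. NATA1 rose 6.62-fold (2.73 ± 0.16, adjusted p = 0.00227), and BGLU18, a glucosidase of ER bodies that releases ABA from its glucose ester, rose 5.76-fold (2.53 ± 0.25). VSP2 and VSP1 rose by 2.49 and 2.34. CYP94C1, which oxidises active jasmonate, was 6.97-fold lower (-2.80 ± 0.14, adjusted p = 0.00227). ERD10, a dehydrin, fell to -1.81 ± 0.26 (adjusted p = 0.0256) and PCC1 to -3.96 ± 0.23, well above background on 1 of 2 line channels.

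AT3G28220 rose by 2.24 in 35S:BBX29 and AT1G52410, which encodes the ER body protein TSA1, by 2.14. Other large rises were those of CAX1, a vacuolar calcium exchanger (2.12), AT14A (2.07) and EXPA8, a cell wall expansin (1.99). Other large falls were those of AT2G25510 (-2.64), PP2-A5 (-2.53), AT5G42530 (-2.50), AT5G62360 (-2.45) and AT4G11393 (-2.19). GA2OX6, which inactivates gibberellin, fell to -2.06 and AT1G68500 to -2.03. AT3G22235 fell by 2.00 and was well above background on 1 of 2 line channels.

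ABA and dehydration effector genes showed 6 lower of 17 members (8 lower adjusted over the list alone, 1 higher and 8 lower with the block). The set fell (median -0.13, camera adjusted p = 0.000419, adjusted p = 0.223 with an estimated correlation). COR47, LEA14 and LTI30, proteins that accumulate on dehydration, fell to -1.57, -1.50 and -1.49, while the galactinol synthase GOLS2 stood at -0.85 (adjusted p = 0.162, 0.00133 with the block) and KIN2 at 0.84 (adjusted p = 0.627, 0.00142 with the block). The cold and CBF regulon showed 1 lower of 12 members (1 higher and 5 lower adjusted over the list alone, 1 higher and 5 lower with the block). These genes were as a group lower (median -0.28, camera adjusted p = 0.00940, adjusted p = 0.342 with an estimated correlation). GOLS3 fell to -1.62, well above background on 1 of 2 line channels, and the zinc finger factors ZAT10 and ZAT12 stood at -1.48 (adjusted p = 0.0829, 1.69e-05 with the block) and -0.80 (adjusted p = 0.175, 0.00212 with the block). Ethylene and ERF genes showed 1 lower of 20 members (1 lower adjusted over the list alone, 5 lower with the block). The list was lower (median -0.16, camera adjusted p = 0.0413, adjusted p = 0.271 with an estimated correlation). ERF5 fell to -0.96, ERF4 stood at -0.67 (adjusted p = 0.169, 0.00410 with the block) and the ethylene synthesis enzyme ACS6 at -0.58 (adjusted p = 0.300, 0.0146 with the block).

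Root hair markers showed 1 lower of 8 members (5 lower adjusted over the list alone, 6 lower with the block). The set was lower (median -0.56, camera adjusted p = 2.01e-06, adjusted p = 0.222 with an estimated correlation). The expansin EXPA18 fell to -0.89, with EXPA7 at -0.68 (adjusted p = 0.0647, 0.00258 with the block) and PRP3 at -0.59 (adjusted p = 0.195, 0.00806 with the block). Iron genes showed 1 lower of 14 members (3 lower adjusted over the list alone, 6 lower with the block). Together they were lower (median -0.27, camera adjusted p = 0.00473, adjusted p = 0.232 with an estimated correlation). NAS4 fell to -1.08, BHLH38 stood at -0.66 (adjusted p = 0.129, 0.00316 with the block) and the ferritin FER3 at -0.55 (adjusted p = 0.428, 0.0380 with the block).

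Heat shock genes showed 1 higher of 9 members (3 higher adjusted over the list alone, 4 higher with the block). The set was higher (median 0.38, camera adjusted p = 0.00163, adjusted p = 0.223 with an estimated correlation). HSP17.6C rose by 1.38, HSP70-4 stood at 0.97 (adjusted p = 0.0703, 0.000266 with the block) and HSP90.1 at 0.78 (adjusted p = 0.300, 0.0113 with the block). PIF targets and growth genes showed 1 higher of 9 members (3 higher adjusted over the list alone, 3 higher with the block). These genes were as a group higher (median 0.23, camera adjusted p = 0.0124, adjusted p = 0.344 with an estimated correlation). The auxin response gene IAA29 rose by 1.60, the cell wall enzyme XTH15 stood at 0.82 (adjusted p = 0.153, 0.00174 with the block) and PIF4 at 0.80 (adjusted p = 0.233, 0.00571 with the block). Antioxidant and glutathione transferase genes showed 1 higher of 13 members (1 higher adjusted over the list alone, 2 higher with the block). The list was higher (median 0.28, camera adjusted p = 0.0124, adjusted p = 0.271 with an estimated correlation). GSTU24 rose by 1.17, and the catalases CAT3 and CAT1 stood at 0.86 (adjusted p = 0.229, 0.00287 with the block) and 0.43 (adjusted p = 0.574). Seed reserve mobilisation genes showed 0 higher and 0 lower of 3 members (1 higher adjusted over the list alone, 1 higher with the block). Together they were higher (median 0.33, camera adjusted p = 0.0249, adjusted p = 0.398 with an estimated correlation), with ICL at 0.68 (adjusted p = 0.0838, 0.00304 with the block) and PCK1 at 0.33 (adjusted p = 0.369).

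The other 16 lists were not called in 35S:BBX29 (camera adjusted p from 0.0698 to 0.868), of which the flavonoid list passed with the block (median 0.17, adjusted p = 0.0486). In the jasmonate list LOX2 rose by 1.66 along with VSP1 and VSP2, and the synthesis enzyme OPR3 fell by 1.00. In the salicylic acid list FMO1 rose by 1.02 while WRKY40 and PR5 fell to -1.28 and -0.91. DIN1 and ASN1 rose by 1.26 and 1.14. RD29A, an ABA-inducible dehydration gene, fell to -1.32 ± 0.20 (adjusted p = 0.0300), SOS1 stood at 0.14 (adjusted p = 0.832), NHX1 at 0.30 (adjusted p = 0.428) and RAB18 at -0.59 (adjusted p = 0.241, 0.0152 with the block). In all, 323 of 21320 genes were called in 35S:BBX29, 134 higher and 189 lower, and 2266 with the block, 1019 higher and 1247 lower. On its own slide 2607 were called, without replicate 1 or 2 of the line 3 and 1, and after median centring in place of loess limma called 0, with 140 at an unadjusted p under 0.05.

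The comparison of 35S:CCA1 with wild type asked which genes follow raised CCA1. CSD2, the chloroplast copper/zinc superoxide dismutase, rose 10.3-fold (3.36 ± 0.14, adjusted p = 0.000602), and XTH15 rose 8.24-fold (3.04 ± 0.21). CYP79F1, an entry enzyme of methionine-derived glucosinolates, was 6.84-fold lower (-2.77 ± 0.29, adjusted p = 0.00433), with -1.68 for the mean of its probes and -5.15 in the deposited value table. MAM1, which lengthens the methionine chain, fell to -2.56 ± 0.18. PCC1 fell to -3.66 ± 0.23 and CYP94C1 to -2.68 ± 0.14.

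Other large rises in 35S:CCA1 were those of AT5G44440 (3.65), AT2G33830, a dormancy-associated gene (3.31), DIN1 (2.94) and ICL (2.83). Rises were also seen for the lipid transfer protein LTP2 (2.77), CCL (2.77) and the lipase MPL1 (2.71). Other large falls were those of AT1G72416 (-2.54), CYP83A1, the next cytochrome of glucosinolate synthesis (-2.43), AT1G05250, a peroxidase (-2.43), AT4G26010 (-2.26), AT5G49350 (-2.23) and IPMI2, an isopropylmalate isomerase (-2.22).

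Glucosinolate synthesis genes showed 7 lower of 18 members (13 lower adjusted over the list alone, 14 lower with the block). The set fell (median -0.64, camera adjusted p = 4.23e-09, adjusted p = 0.222 with an estimated correlation). The aminotransferase BCAT4 fell to -1.85, and the sulphotransferase SOT18 and MYB29 stood at -0.93 (adjusted p = 0.108, 0.00136 with the block) and -0.73 (adjusted p = 0.0675, 0.00263 with the block). The jasmonate list showed 6 lower of 18 members (9 lower adjusted over the list alone, 12 lower with the block). The set fell (median -0.54, camera adjusted p = 4.92e-05, adjusted p = 0.222 with an estimated correlation). The lipoxygenases LOX3 and LOX4 fell to -1.69 and -1.47, OPR3 to -1.58 and the repressor JAZ7 to -1.09, with JAZ1 at -0.71 (adjusted p = 0.193, 0.0259 with the block) and JAZ5 at -0.63 (adjusted p = 0.119, 0.00339 with the block).

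Root hair markers showed 7 lower of 8 members (8 lower adjusted over the list alone). The set fell (median -1.42, camera adjusted p = 1.84e-10, adjusted p = 0.211 with an estimated correlation). The expansins EXPA18 and EXPA7 fell to -1.79 and -1.56, the cell wall proteins PRP3 and COBL9 to -1.68 and -1.53, and the hair regulator RSL4 stood at -0.80 (adjusted p = 0.107, 0.000775 with the block). Phosphate starvation genes showed 3 lower of 6 members (5 lower adjusted over the list alone, 5 lower with the block). These genes were as a group lower (median -1.17, camera adjusted p = 4.92e-05, adjusted p = 0.222 with an estimated correlation). AT4 and SPX1, a phosphate sensor, fell to -1.67 and -1.28, and IPS1, well above background on neither line channel, was at least 2.19-fold lower, while PHT1;1 stood at -1.20 (adjusted p = 0.0938, 3.23e-05 with the block) and SQD2 at -0.62 (adjusted p = 0.196, 0.00969 with the block). The suberin enzymes CYP86A1, GPAT5 and FAR5 fell to -1.93, -1.73 and -1.56, and the fatty acyl reductase FAR1 rose by 1.83, in a list that was not called (adjusted p = 0.158). The phosphate genes, CYP86A1, GPAT5 and FAR5 were lower in the same line as the root hair markers (median -1.42). So were 15 genes of other root tissues, CYP86A1 and GPAT5 among them (median -0.92), while FAR1 moved the other way. In 35S:ERF019 the phosphate list (median -0.46), CYP86A1 (-1.29) and GPAT5 (-0.93) were lower without a call for root hair markers (median -0.17). In 35S:BBX29 root hair markers were lower (median -0.56) and the phosphate list was not called (median -0.04).

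PIF targets and growth genes showed 5 higher of 9 members (6 higher adjusted over the list alone). The set rose (median 0.80, camera adjusted p = 4.92e-05, adjusted p = 0.233 with an estimated correlation). The auxin response genes IAA29 and IAA19 rose by 2.47 and 0.85, PIL1 by 0.80, well above background on 1 of 2 wild type channels, PIF4 stood at 0.91 (adjusted p = 0.0832, 0.00123 with the block) and ATHB2 at 0.12 (adjusted p = 0.688). Antioxidant and glutathione transferase genes showed 4 higher and 1 lower of 13 members (4 higher and 1 lower adjusted over the list alone, 7 higher and 1 lower with the block). The list was higher (median 0.48, camera adjusted p = 0.0361, adjusted p = 0.332 with an estimated correlation). The cytosolic superoxide dismutase CSD1 rose by 2.25, CAT3 by 1.29 and GSTF2 by 1.15, with GSTF6 at 0.59 (adjusted p = 0.217, 0.00523 with the block) and GSTU24 at 0.52 (adjusted p = 0.179, 0.0226 with the block). Dark and sugar starvation genes showed 2 higher of 4 members (2 higher adjusted over the list alone). Together they were higher (median 0.84, camera adjusted p = 0.00163, adjusted p = 0.223 with an estimated correlation). ASN1 rose by 1.23, DIN10 stood at 0.44 (adjusted p = 0.432, 0.0342 with the block) and DIN11 at 0.22 (adjusted p = 0.580). Seed reserve mobilisation genes showed 2 higher of 3 members (3 higher adjusted over the list alone). These genes were as a group higher (median 1.16, camera adjusted p = 0.000226, adjusted p = 0.271 with an estimated correlation), MLS, the malate synthase, among them (1.16), with PCK1 at 0.54 (adjusted p = 0.0585, 0.00590 with the block).

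ABA and dehydration effector genes showed 2 lower of 17 members (4 lower adjusted over the list alone, 6 lower with the block). The list was lower (median -0.24, camera adjusted p = 0.00759, adjusted p = 0.233 with an estimated correlation). ERD10 fell to -1.61 and GOLS1 to -0.97, with LEA14 at -1.12 (adjusted p = 0.0550, 0.000957 with the block) and COR47 at -0.60 (adjusted p = 0.0881, 0.00355 with the block). The cold and CBF regulon showed 2 lower of 12 members (3 lower adjusted over the list alone, 6 lower with the block). Together they were lower (median -0.26, camera adjusted p = 0.0240, adjusted p = 0.375 with an estimated correlation), with falls of GOLS3 (-1.40) and the CBF relative DDF1 (-1.27), ZAT10 at -1.26 (adjusted p = 0.0626, 1.75e-05 with the block) and ZAT12 at -0.63 (adjusted p = 0.164, 0.00485 with the block). Of the salt genes SOS3, a calcium sensor for sodium export, fell to -0.75, while SOS1 stood at 0.26 (adjusted p = 0.377), NHX1 at 0.25 (adjusted p = 0.340), RD29A at -0.23 (adjusted p = 0.590) and RAB18 at -0.31 (adjusted p = 0.416).

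The named clock genes did not pass the test in 35S:CCA1 without the block. The sample details used here give no time of day of harvest, and the fit recovered 29.3% of simulated log2 changes of 1. A lack of a call therefore does not show that the clock genes were unchanged. LHY, the closest relative of CCA1, stood at -0.23 (adjusted p = 0.539), TOC1 at 0.09 (adjusted p = 0.823), GI at 0.04 (adjusted p = 0.916), PRR7 at 0.35 (adjusted p = 0.409), PRR5 at 0.36 (adjusted p = 0.392), ELF4 at 0.22 (adjusted p = 0.406) and LUX at -0.04 (adjusted p = 0.941). The morning-phased list (0 of 11 called, 1 lower with the block, median -0.13, camera adjusted p = 0.702) and the evening-phased list (0 of 12, 3 higher with the block, median 0.21, camera adjusted p = 0.0731) were not called, nor were 13 others, 15 in all (camera adjusted p from 0.0731 to 0.910). Members called in these were the ethylene genes ETR2 (1.21), ERS2 (0.82) and ERF5 (-0.80), the stress factor NAC019 (0.89), PR5 (-1.23), WRKY40 (-0.77) and PR2 (-0.75, well above background on 1 of 2 line channels). DFR of anthocyanin synthesis (-1.01), the starch synthase GBSS1 (-1.64) and NAS4 (-1.26) fell, and BBX20 (0.64), DPE1 of starch breakdown (1.08) and the iron regulator PYE (0.73) rose.

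Across the array, 1332 of 21320 genes were called in 35S:CCA1, 701 higher and 631 lower, and 4856 with the block, 2538 higher and 2318 lower. On the arrays of its own slide alone 405 were called, without replicate 1 or 2 of the line 509 and 536, and after median centring in place of loess limma called 0, with 377 at an unadjusted p under 0.05.

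**Figure D2:**
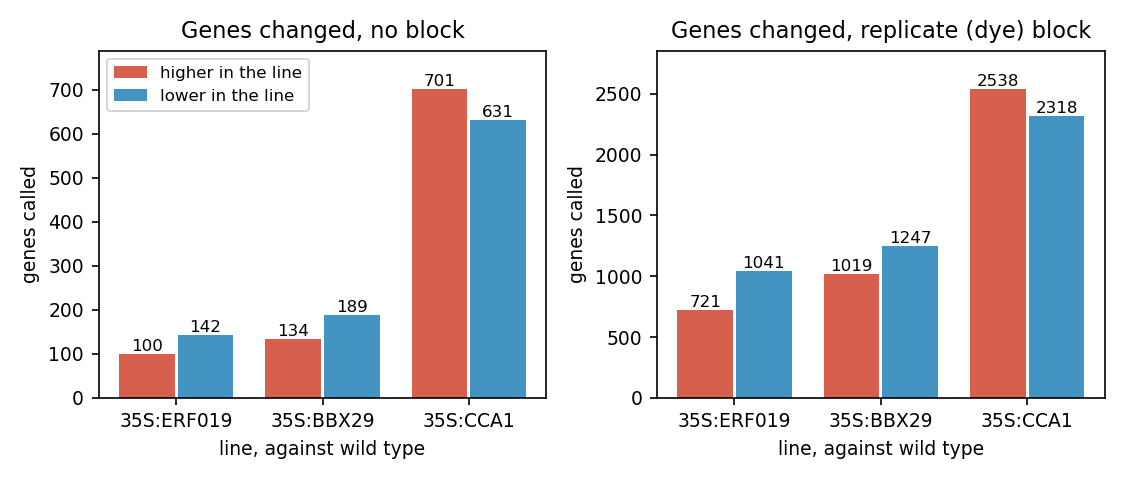
Number of genes called higher (red bars) and lower (blue bars) than wild type in each line, at an adjusted p under 0.05, for the fit without a block (left) and with the replicate number, which is the dye orientation, as a block (right, another scale). 35S:CCA1 had the most calls in both fits, 701 higher and 631 lower without the block.

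**Figure D3:**
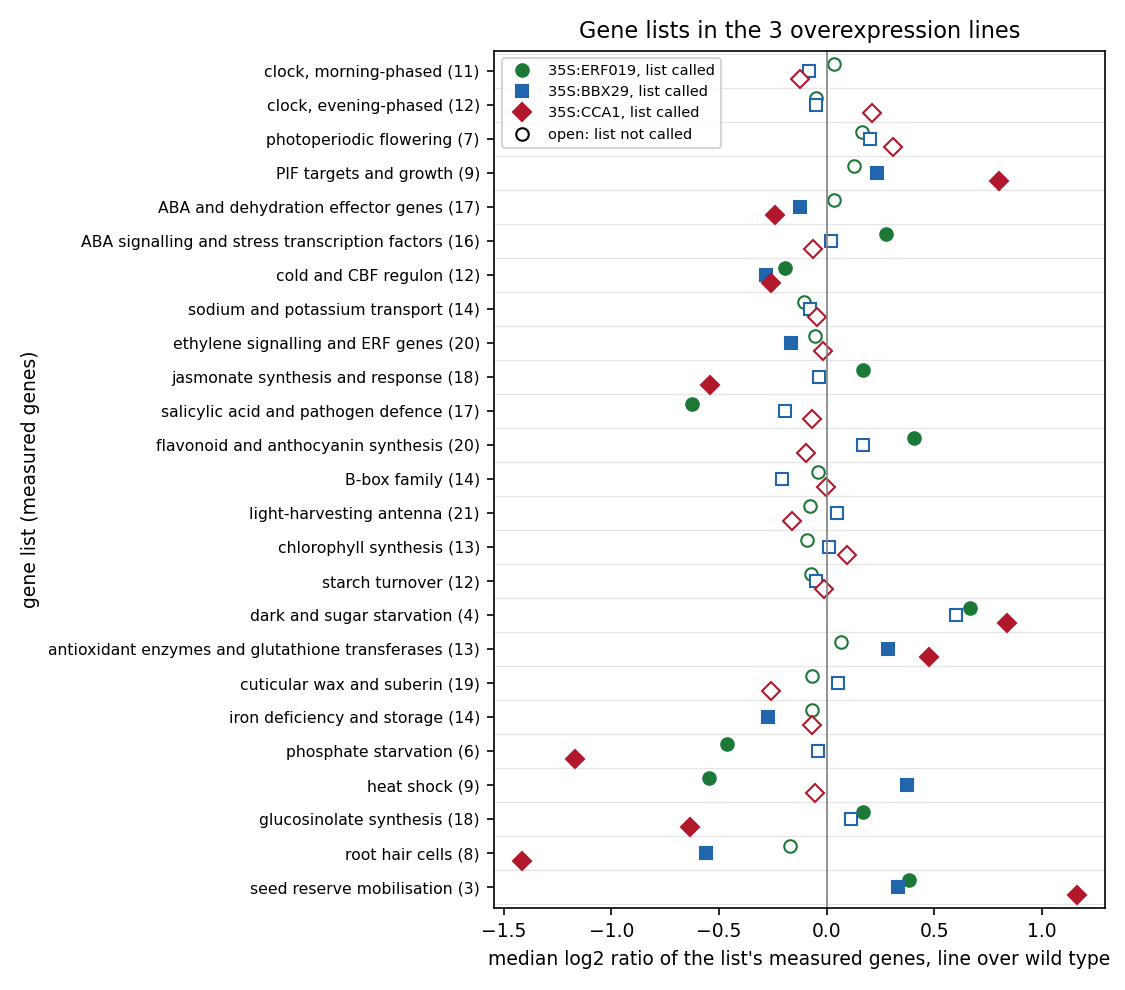
Median log2 ratio of line over wild type (horizontal axis) of the measured genes of each list (vertical axis, number of genes in brackets), with circles for 35S:ERF019, squares for 35S:BBX29 and diamonds for 35S:CCA1. Filled points were called by camera at the preset correlation, none held with an estimated one, and root hair markers in 35S:CCA1 lie lowest at -1.42.

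The next comparison asked which changes the lines shared. PCC1, CYP94C1, WRKY40 and PR5 fell and EXPA8, DIN1, CCL and ASN1 rose in all 3 lines. In all, 58 genes were called the same way in the 3 lines, 17 higher and 41 lower, and 633 with the block. CYP94C1 fell to -0.87 in 35S:ERF019, -2.80 in 35S:BBX29 and -2.68 in 35S:CCA1, and EXPA8 rose by 1.23, 1.99 and 2.67. The gibberellin-inactivating GA2OX6 (-1.07, -2.06 and -1.35), the zinc transporter ZIP3 (-0.87, -1.36 and -2.18) and the calmodulin-like CML37 (-1.57, -1.40 and -1.27) fell in 35S:ERF019, 35S:BBX29 and 35S:CCA1. The auxin gene SAUR19 rose by 0.81, 1.24 and 1.69. These shared genes were picked by size and known function after their values were seen.

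**Figure D4:**
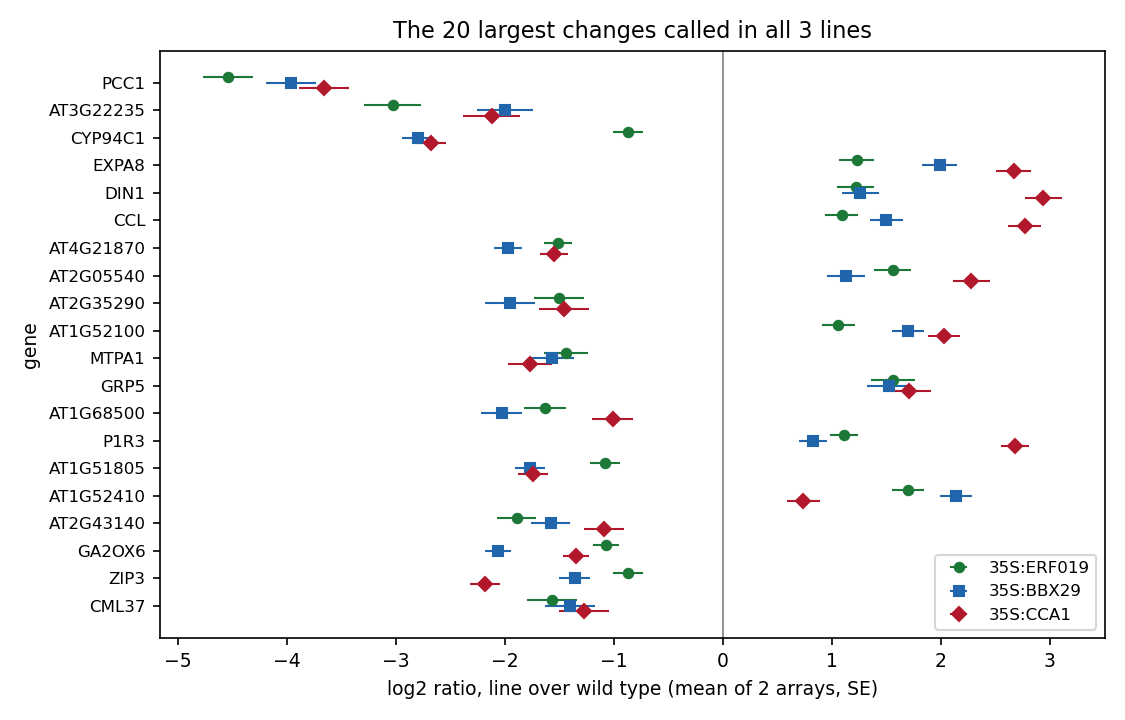
Log2 ratio of line over wild type (horizontal axis, mean of 2 arrays with its standard error) of the 20 genes with a locus identifier and the largest mean change among those called the same way in all 3 lines (vertical axis), with circles for 35S:ERF019, squares for 35S:BBX29 and diamonds for 35S:CCA1. PCC1 had the largest mean change of these, at -4.54, -3.96 and -3.66.

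Taken by pairs, 91 genes changed the same way in 35S:ERF019 and 35S:BBX29 (825 with the block) and 1 the opposite way, 124 in 35S:ERF019 and 35S:CCA1 (1034 with the block) and 11 opposite, and 195 in 35S:BBX29 and 35S:CCA1 (1505 with the block) and 5 opposite. Lists of these sizes drawn independently would share 1.89, 7.49 and 10 genes the same way. Unchanged lines sharing wild type RNA gave a mean of 0, 0.01 and 0 such genes over 100 simulations, in which line and wild type RNA varied equally. The fit calls few unchanged genes, so this count has little room to rise. Across genes, which are not independent replicates, the log2 ratios correlated at r = 0.554, 0.493 and 0.596 for these pairs against 0.501 in the simulation. Their covariance was 0.0483, 0.0559 and 0.0746 against simulated values of 0.0234 in each pair, and 0.0466 if all spread between arrays came from wild type RNA. Splitting the wild type samples would leave 1 array per line, so this was not done, and part of the excess may come from shared wild type RNA.

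The last comparison asked where the lines differed. CYP79F1 was 3.84 higher in 35S:ERF019 than in 35S:CCA1, and MAM1 was 2.61 higher in 35S:BBX29 than in 35S:CCA1. CSD2 differed from 35S:CCA1 by -2.88 in 35S:ERF019 and -3.23 in 35S:BBX29. AT5G61620 was 2.53 higher in 35S:ERF019 than in 35S:BBX29 and 2.43 higher than in 35S:CCA1. By the test of the difference itself, 4 genes differed between 35S:ERF019 and 35S:BBX29, 93 between 35S:ERF019 and 35S:CCA1 and 43 between 35S:BBX29 and 35S:CCA1. With the block these counts were 424, 1191 and 801. Of the lists, 11, 13 and 12 differed in these pairs, and 0 in each pair with an estimated correlation. With the block the iron list also differed between 35S:BBX29 and 35S:CCA1 (median -0.32, adjusted p = 0.0692, 0.0254 with the block). With the spread taken from the slide that 35S:ERF019 and 35S:CCA1 share, 1 gene differed between them, at unchanged log2 differences. 35S:BBX29 lay alone on its slide, so its differences from the other lines were not compared within a slide.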

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

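The tests for wild type spread and dye bias were chosen only after the results they address were seen. Each value in this paragraph and the next is a log2 difference between the effects of 2 lines, past an adjusted p of 0.05 in limma's test of the difference itself. Between 35S:ERF019 and 35S:BBX29 (35S:ERF019 minus 35S:BBX29), the transgene transcripts BBX29 (-6.41) and ERF019 (5.73) differed, as did AT5G61620 (2.53). Between 35S:ERF019 and 35S:CCA1 the transgene transcripts differed by 6.31 for ERF019 and -5.98 for CCA1. The glucosinolate genes CYP79F1 (3.84), MAM1 (3.18), IPMI2 (2.78) and CYP83A1 (2.71) were higher in 35S:ERF019 than in 35S:CCA1, as were the jasmonate-linked CORI3 (2.63), VSP1 (1.80), CYP94C1 (1.80) and OPR3 (1.64). AT5G61620 (2.43), AT4G26010 (2.01), AT3G43270 (1.91) and the root hair expansins EXPA18 (1.84) and EXPA7 (1.63) were higher as well. Lower in 35S:ERF019 than in 35S:CCA1 were XTH15 (-3.74), AT5G44440 (-3.66), AT2G33830 (-2.89), CSD2 (-2.88), IAA29 (-2.35), GSTF2 (-2.10), DIN1 (-1.72), FAR1 (-1.71) and CCL (-1.67). With the spread taken from the slide these lines share, 1 gene differed in place of 93. Each line's log2 ratio is the mean of its own 2 arrays in either fit, so the differences were the same. Only the estimate of the spread changed, with 2 residual and 3.35 prior degrees of freedom against 3 and 4.03.

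Between 35S:BBX29 and 35S:CCA1, which lay on different slides, the transgene transcripts differed by 6.66 for BBX29 and -5.93 for CCA1. Higher in 35S:BBX29 were MAM1 (2.61), NATA1 (2.36), CYP83A1 (2.36), AT5G49350 (2.21), VSP1 (2.05), IPMI2 (1.94), AT1G05250 (1.84) and the suberin genes CYP86A1 (1.68) and GPAT5 (1.53). Lower in 35S:BBX29 were AT5G44440 (-3.74), CSD2 (-3.23), AT2G33830 (-2.36) and ICL (-2.15). CCA1, MAM1, CYP83A1, VSP1, IPMI2, AT5G44440, CSD2 and AT2G33830 also differed in the same direction between 35S:ERF019 and 35S:CCA1, which lay on 1 slide, with the spread taken from all 6 arrays. The other genes here were not called in that comparison. Both comparisons subtract the log2 ratios of the same 35S:CCA1 arrays, so a shared direction is not independent evidence.

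Lists that differed by camera and held a member past the gene test are given as the median log2 difference. Between 35S:ERF019 and 35S:CCA1 these were PIF targets and growth (-0.19, adjusted p = 0.00362), jasmonate (0.90, adjusted p = 1.18e-15), dark and sugar starvation (-0.65, adjusted p = 0.0120), antioxidant enzymes (-0.39, adjusted p = 0.00467), glucosinolates (0.74, adjusted p = 2.99e-15) and root hairs (1.25, adjusted p = 4.68e-14). Between 35S:BBX29 and 35S:CCA1 they were jasmonate (0.46, adjusted p = 1.89e-10), wax and suberin (0.12, adjusted p = 0.0283), glucosinolates (0.98, adjusted p = 1.39e-18) and seed reserve mobilisation (-1.01, adjusted p = 6.47e-05). With an estimated correlation none of these 10 held. The lowest adjusted p with an estimated correlation was 0.0668, reached by jasmonate and glucosinolates in both pairs and by root hairs.

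PCC1, CYP94C1, EXPA8 and 55 other genes changed the same way in all 3 lines, 58 in all. Spread between wild type samples that the lines shared was tested against the largest covariance between lines it could give, 0.0466. The lowest observed covariance was 0.0483, 0.938 bootstrap standard errors above, and the highest lay 14.2 above. These standard errors are taken across genes, which are not independent replicates, and do not measure spread between samples. Shared wild type RNA therefore cannot be told apart from an effect of the lines. Wild type seedlings that differed as a whole from all 3 lines, by growth, harvest or seed batch, could give such genes too, and 5 of the 58 also differed between lines, 18 of the 58 and 136 of 633 shared genes with the block, which leaves this open because the wild type of each array is not identified. A response common to overexpressing these factors was not tested, as no line with another transgene was compared.

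Root hair genes were lower in 35S:CCA1, with 7 of 8 called and a median of -1.42. For uneven dye bias of the root hair probes, 8 of 8 genes were lower on both arrays, 1 per dye orientation. The line's mean already balances the dyes, and 7 of the 8 had been called lower on these same arrays. The count therefore had little room to come out otherwise, and no conclusion is drawn from it. A smaller share of root in the 35S:CCA1 seedlings would lower other root genes by about as much. The list of such genes was written after the changed genes had been seen, so it is not independent evidence. CYP86A1 (-1.93) and GPAT5 (-1.73) were on it. The 15 tested had a median of -0.92 (95% interval from -1.09 to 0.00). Of these 9 fell, TIP2;3 (-1.49) among them, while the root transcripts SKOR (0.10), SHR (-0.10), CASP5 (0.00) and MYB36 (0.02) were not called, and SCR (0.56, adjusted p = 0.0161) and ASFT (-0.55, adjusted p = 0.0126) passed with the block. The difference between the 2 medians was 0.50 with a 95% interval from -0.11 to 1.43. Both intervals resample genes, which are not independent replicates, and do not measure spread between samples. A smaller share of root and a lower expression in root hairs therefore cannot be told apart.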

How the results depend on the processing

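The alternatives were chosen before the data were examined. Of 133 called results for named genes, limma's call was kept for all 133 with the replicate block, and 51 further named results passed with it. The call was lost for 133 after median centring in place of loess, 52 on the arrays of the line's own slide, 9 on the line's 2 arrays, 8 without background subtraction, 3 with scanner processed signals, 1 with the value table, 9 without a filter, 10 of the 120 still measured under the strict filter, and 1 with the mean of probes. With 1 array left out, the call was lost for 89 and 90 without 35S:BBX29 replicate 1 or 2, 28 and 25 without 35S:ERF019 replicate 1 or 2, and 18 and 16 without 35S:CCA1 replicate 1 or 2. Among the genes named by the rule and the lists fixed before the data were examined, the replicate block changed no other call than those given beside the results. Of 29 list calls, 29 were lost with an estimated correlation, 6 of the 26 still tested with the strict filter, 4 with the value table, 4 with the mean of probes, 3 with processed signals, 2 with median centring and 1 with the replicate block (dark and sugar starvation in 35S:ERF019). Without replicate 1 or 2, 2 and 3 list calls were lost for 35S:ERF019 arrays, 4 and 1 for 35S:BBX29 and 2 and 1 for 35S:CCA1. The seed reserve list in 35S:BBX29 lost its call in 9 of 17 alternatives. The seed reserve mobilisation list had too few genes under the strict filter and has no value there in any of the 3 lines. No result changed direction while called. The log2 ratios of 28 of the 133 were larger by over 1.5 times with scanner processed signals, 28 with the value table, and smaller by over 1.5 times for 7 with the mean of probes and 2 with the strict filter. Over all alternatives CYP79F1 in 35S:CCA1 ranged from -5.15 to -1.68, AT5G44440 from 3.19 to 6.13 and IPS1 from -4.93 to -0.93. The median of the cold list in 35S:CCA1 turned from -0.26 to 0.02 under the strict filter, where its call was lost. The promoter motif test and its alternative with shorter promoters were not run, since no genome sequence was used. Signal over background limits dim genes: the strict filter tested 16560 of 21320 genes.

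Values below that moved by over 1.5 times are given in the order 35S:ERF019, 35S:BBX29, 35S:CCA1, and pairs in the order 35S:ERF019 with 35S:BBX29, 35S:ERF019 with 35S:CCA1, 35S:BBX29 with 35S:CCA1. With the replicate block, 1762, 2266 and 4856 genes changed, 424, 1191 and 801 differed between lines, 825, 1034 and 1505 changed the same way in pairs, and 633 in all 3 lines. With the replicate block within slide these were 4707, 6394 and 9226, then 2410, 4416 and 3437, then 2461, 2813 and 4038, and 1910, with 1 residual degree of freedom. On only the arrays of the line's own slide, 5, 2607 and 405 genes changed, 1 differed between 35S:ERF019 and 35S:CCA1, and 3 changed the same way in either pair with 35S:ERF019 and 3 in all 3 lines. Differences from 35S:BBX29 have no value there, and with only the 2 arrays of the line no difference between lines was computed. On those 2 arrays 493, 2607 and 872 genes changed, 293 in 35S:ERF019 with 35S:BBX29 and 535 in 35S:BBX29 with 35S:CCA1 the same way, and 124 in all 3 lines.

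Without background subtraction 8 genes differed between 35S:ERF019 and 35S:BBX29. With scanner processed signals, median centred, 837, 1711 and 3203 genes changed, 41, 451 and 278 differed, 391, 465 and 1009 changed the same way in pairs, and 271 in all 3 lines. With the deposited value table these were 1693, 3443 and 5239, then 270, 1113 and 694, then 910, 996 and 2121, and 670. With median centring in place of loess, limma called 0 genes in each line (137, 140 and 377 at an unadjusted p under 0.05), 0 differences and 0 shared genes. The target transcripts then stood at 4.83, 6.15 and 5.57 without a call, and the median standard error was 0.476 against 0.162 with loess. The strict filter gave 128 changed genes in 35S:ERF019, 2, 54 and 26 differences, 53 and 71 genes the same way in the pairs with 35S:ERF019, 33 in all 3 lines, and 5 lists in 35S:BBX29. The mean of all kept probes gave 10, 166 and 109 differences, 139 and 196 genes the same way in the pairs with 35S:ERF019, and 99 in all 3 lines. An adjusted p under 0.10 gave 472, 599 and 2189 changed genes, a minimum change of 1 on the log2 scale gave 589 in 35S:CCA1, and an estimated correlation in camera gave 0 lists in each line. Fits on fewer arrays that keep both arrays of a line leave its log2 ratios unchanged, so only the estimate of the spread differs. The cause was not tested for fits that drop an array of the line itself, the processed signals, the value table, the mean of probes or the absence of background subtraction.

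With 1 array left out, its line keeps a lone array that is assumed to vary like the others, and changed genes ranged from 5 to 386, 1 to 503 and 405 to 1471. Differences ranged from 1 to 23, 1 to 73 and 2 to 66, genes changed the same way from 0 to 147, 3 to 108 and 0 to 233, and in all 3 lines from 0 to 48. Lists called ranged from 7 to 10, 6 to 9 and 8 to 10, and the targets from 4.31 to 5.16, 5.81 to 6.76 and 5.56 to 5.89. Without 35S:ERF019 replicate 1 or 2, 9 and 14 genes changed in that line. Without 35S:BBX29 replicate 1 or 2, 3 and 1 changed in that line, and without either one 5 in 35S:ERF019 and 405 in 35S:CCA1. Without 35S:CCA1 replicate 1 or 2, 509 and 536 changed in that line, and without either one 386 in 35S:ERF019 and 503 in 35S:BBX29.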

Other observations

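The copper test and the 6 lists here were chosen after the changed genes had been seen, so they are not independent evidence. They were adjusted over fewer results than the fixed lists, so their adjusted p-values cannot be ranked against those. With an estimated correlation their lowest unadjusted camera p was 0.00575. The fixed lists of salicylic acid in 35S:ERF019 (0.00494) and root hairs in 35S:CCA1 (0.00563) had lower values and were not called. Genes induced by sulphur deficiency showed 8 lower of 11 in 35S:CCA1 (median -1.05, adjusted p = 0.0419 with an estimated correlation). LSU1 fell to -2.05, the sulphate transporter SULTR1;2 to -1.56 and SDI1, a repressor of glucosinolate synthesis, to -1.49. In 35S:ERF019 the same list showed 1 lower of 11, 5 with the block (median -0.52, adjusted p = 0.0419 with an estimated correlation), LSU1 (-1.38), and in 35S:BBX29 1 lower, SULTR1;2 (-1.34), and 3 with the block (list median -0.27, adjusted p = 0.162 with an estimated correlation). Genes induced by zinc deficiency showed 1, 3 and 2 lower of 7 in 35S:ERF019, 35S:BBX29 and 35S:CCA1, and 6 in each line with the block (medians -0.67, -1.06 and -0.73, each with an adjusted p of 0.0419 with an estimated correlation). The zinc transporter ZIP3 fell in each line, ZIP4 fell to -1.49 in 35S:BBX29 and ZIP9 to -2.15 in 35S:CCA1. Root hair markers were lower too in 35S:BBX29 (median -0.56) and 35S:CCA1 (median -1.42), and were not called in 35S:ERF019 (median -0.17).

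Genes of the ER body and myrosinase system, whose glucosidases activate defence compounds, showed 4 higher of 10 in 35S:ERF019 (median 0.37) and 4 higher, 7 with the block, in 35S:BBX29 (median 0.72), each with an adjusted p of 0.0419 with an estimated correlation. BGLU18 and TSA1 rose by 1.72 and 1.70 in 35S:ERF019. In 35S:CCA1 the list showed 2 higher and 1 lower, 6 and 1 with the block (median 0.44, adjusted p = 0.171 with an estimated correlation), with ESM1 higher and ESP, which alters glucosinolate breakdown, at -0.80. Genes of root tissues other than hairs showed 2, 1 and 9 lower of 15 in 35S:ERF019, 35S:BBX29 and 35S:CCA1, with the block 6, 4 and 10 lower and 1, 0 and 1 higher (medians -0.26, -0.20 and -0.92, adjusted p = 0.203, 0.178 and 0.108 with an estimated correlation). The lists induced by sulphur (median -1.05), zinc (median -0.73) and copper deficiency (median -1.47) were lower in 35S:CCA1, as were root hair markers (median -1.42). Whether they moved together was not tested. In 35S:ERF019 the sulphur (median -0.52) and zinc (median -0.67) lists were lower without a call for root hair markers. Genes for copper proteins repressed by microRNAs showed 3 higher and 2 lower of 10 in 35S:CCA1, 5 and 2 with the block (median 0.32, adjusted p = 0.203 with an estimated correlation) and 1 higher in each of 35S:ERF019 and 35S:BBX29, with the block 4 and 3 higher and 1 lower in each (medians 0.28 and 0.22). Genes induced by copper deficiency showed 1 lower of 7 in each of these lines, 1 and 4 with the block (medians -0.30 and -0.42). No copper list was called with an estimated correlation in any of the 3 lines.

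In 35S:CCA1 the superoxide dismutases CSD1 and CSD2 and their copper chaperone CCS rose by 2.25, 3.36 and 1.77, and the iron superoxide dismutase FSD1 fell to -0.97. Of 7 genes induced by copper deficiency 6 fell (median -1.47, adjusted p = 0.0544 with an estimated correlation in camera), with the reductases FRO4 (-1.61) and FRO5 (-1.57), the transporter COPT2 (-1.41) and FSD1 among them. A copper status that differs between 35S:CCA1 and wild type seedlings could move both sets, since copper-responsive microRNAs repress CSD1, CSD2 and laccase transcripts when copper is scarce. By fry the deficiency-induced genes moved one way (adjusted p = 0.00192), but 8 microRNA-repressed genes without CSD2 and LAC12 did not pass (median 0.08, adjusted p = 0.0784), and the laccases LAC3 (-0.92) and LAC13 (-0.76) fell. Copper status therefore stays open.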
